A study of Homo sapiens with 12 samples.

How the data were processed

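Gene expression was measured in HEK293T cells, a human embryonic kidney cell line, on 12 two-colour Agilent arrays. Cells carried a control siRNA or an siRNA against TNIK at 15 nM for 72 h and then received Wnt3A or control medium (CM). Each array compared 2 RNA extracts, 1 labelled with Cy5 and 1 with Cy3, and each pair of extracts was hybridised again with the dyes exchanged. The 12 arrays therefore held 6 extract pairs. In 3 pairs Wnt3A was compared with CM in si-control cells, at 4 h, 7 h and 9 h. In the other 3 pairs si-TNIK was compared with si-control cells under Wnt3A, at 4 h and in Experiments 1 and 2 at 7 h. The 2 arrays of a pair were counted as 1 replicate. Nothing in the labels or files shows separate cultures for the pairs except for the 2 experiments at 7 h, so p-values across pairs may measure technical spread in part.

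Per the file headers, the array images were read with Agilent Feature Extraction 10.5.1.1; per the submitters' processing notes, the version was 8.5.1.1. Each deposited scanner file held 45015 spots, of which 43376 were not control spots and covered 41000 probes. The deposited scanner files give the median pixel intensity of each spot and of its local background in both colours, a processed intensity, quality marks and a log10 ratio of red over green. The mean pixel intensity, chosen before the data were examined as the starting value, was not in the files, and the median pixel intensity was used in its place. The values the authors deposited in the series table were compared with the log10 ratios of the scanner files. They were the same ratios with the sign turned on the 6 swapped arrays, so they gave treated over control on the log10 scale.

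Spot and background intensities were corrected with the normexp method of limma 3.58.1 in R 4.3.3 (offset 50), and red and green were balanced within each array by loess. Control spots and spots the scanner software had marked as outliers had no weight, and the marked spots were left out of the averages. Ratios were turned to treated over control on the log2 scale, spots of 1 probe were averaged, and the mean of the 2 dye-swapped arrays was taken as the value of the pair, which cancels a dye effect of constant size. A probe was kept when its signal was well above background in either colour on both arrays of at least 1 pair, and 35436 probes were kept. Gene symbols came from matching the transcript accessions in the files to a RefSeq gene table of assembly GRCh38.p14, with accession versions ignored. This paired 25398 of the 41000 probes with 1 symbol and left 15602 without a symbol. The file headers name an older genome build, so no coordinates are given. For each symbol the brightest probe was used, and probes without a symbol were kept as features of their own. In all, 28169 features were tested, 16017 with a symbol and 12152 without. No probe could be paired with TNIK, so the knockdown itself could not be read from a named gene.

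The 6 pair values of each feature were fitted in limma with 1 coefficient for the 3 Wnt3A pairs and 1 for the 3 knockdown pairs (4 residual degrees of freedom). A further fit had the Wnt3A response as a line over hours and the knockdown at 4 h and at 7 h as separate coefficients (2 residual degrees of freedom). It gave the change of the Wnt3A response per hour, the knockdown effect at 7 h and the difference between 7 h and 4 h. Tests were two-sided, and a feature was called at a Benjamini-Hochberg adjusted p under 0.05 over all features. Errors given with a fold change are standard deviations over the 3 pairs of its comparison. The comparisons, the tests, the gene lists, the rule for named genes and most of the alternative settings were chosen before the data were examined, except where stated.

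Named genes were, for each averaged comparison, the 6 named genes of lowest p per direction among those with the same direction on all 6 arrays, since none was called. From each gene list, 2 members of lowest p per comparison could be named. The 2 probes without a symbol that are named in the knockdown were chosen after their values were seen, as were AXIN2, MYC and MSX2. Of the 47 genes the rule named for Wnt3A, 18 had more than 1 probe, and in 4 of these the probes differed in sign (CREBBP, LDHA, RPS15 and TUBB3). In the knockdown the probes differed in sign in 11 of 22 such genes (BBC3, CCN4, COL6A1, CTSC, IER5, MAP4K4, MINK1, PPARD, PTPN18, RPS15 and TUBB3).

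There were 19 gene lists with 457 gene entries: Wnt feedback and stem cell targets, other reported Wnt targets, Wnt pathway components, TNIK and related kinases, AP-1 and immediate early genes, interferon response, G2/M genes, G1/S genes, p53 targets, cholesterol and fatty acid synthesis, unfolded protein and amino acid response, actin and SRF or YAP targets, TGF-beta and BMP targets, hypoxia and glycolysis, Notch targets, histone genes, ribosomal proteins as a sign of RNA quality, and markers of fibroblasts and of neurons as other cell types. The 18 lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the lists. The tests were repeated with an estimated correlation and with fry. Some genes stand in more than 1 list, such as ID2.

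Depth is given for arrays as signal over background, and the number of arrays limits the precision. On simulated data with the fitted noise and 28169 features, changes of log2 0.5 were called in 50 of 50 genes for the Wnt3A response and in 50 of 50 for the knockdown average. They were called in 48 of 50 genes for the knockdown at 7 h, but in only 19 of 50 for 7 h minus 4 h and in only 6 of 50 for the change per hour, where the size is that from 4 h to 9 h. A simulated change of log2 1 was called in 50 of 50 genes for 7 h minus 4 h and in 48 of 50 for the change per hour. Over all simulated sizes, false calls were 13 beside 200 recovered genes for the Wnt3A response and 11 beside 200 for the knockdown average. They were 30 beside 198 for the knockdown at 7 h, 33 beside 169 for 7 h minus 4 h and 23 beside 154 for the change per hour, or 13.2%, 16.3% and 13.0% of the calls. Simulated noise was independent between pairs, which the real pairs may not be. For the averages each simulated change had the same size in all 3 pairs, and 200 genes changed at once. Real changes may vary between pairs, so these counts do not show that a real change of log2 0.5 would be called. TNFRSF12A, at 0.54 with Wnt3A, was not called. A shift of 0.1 in the Wnt feedback and stem cell targets was called in 20 of 20 draws, and an unshifted list in 0 of 20. Genes were independent of each other in these draws. In the data the estimated correlation was -0.03 in this list. Over the tested lists it ran from -0.07 for Notch targets to 0.87 for the unfolded protein and amino acid response. The draws therefore do not show how often camera calls an unshifted list of correlated genes.

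Alternative settings chosen at that stage were no background correction, the processed intensities, median centring in place of loess, the deposited log ratios, the series table, quantile normalization of brightness, no filter, a strict filter, the mean over the probes of a gene, 1 dye orientation alone, robust variance settings, all 12 arrays with the pair as a block, the slide as a block, the 3 pairs of a comparison alone, 1 coefficient per time point, equal weight per time point, an adjusted p under 0.1, a fold of at least 1.5 with the same direction on all arrays, and leaving out each pair in turn. Alternatives with the scan day as a block, without the pairs of scan day 2, and with dye effects regressed out were added after seeing the data, as were the gene lists under most scalings. The headers place the arrays on 4 slides and 2 scan days. Each slide held 1 comparison, so a fixed slide term could not be fitted beside it. Plots were drawn with matplotlib 3.10.9.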

Results

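The experiment addressed which genes answer to Wnt3A in HEK293T cells and whether lowering TNIK, a kinase, alters that answer. Expression was compared in 6 extract pairs on 12 arrays: 3 pairs of Wnt3A over CM in si-control cells at 4 h, 7 h and 9 h, and 3 pairs of si-TNIK over si-control cells under Wnt3A, 1 at 4 h and 2 at 7 h. Each time point of the Wnt3A series was therefore a single pair. Median green intensities ran from 140 to 224.5 over local backgrounds of 51.5 to 63, and median red intensities from 169 to 291 over backgrounds of 131 to 135. No spot was saturated. The Wnt3A 9 h pair and knockdown Experiment 2 were scanned on a second day and were dimmer, with green medians of 140 to 173 against 193 to 224.5 in the others. Fold changes were small: the standard deviation of log2 fold changes over features was 0.10, 0.17 and 0.17 in the Wnt3A pairs at 4 h, 7 h and 9 h. It was 0.12, 0.15 and 0.13 in the knockdown pairs at 4 h and in Experiments 1 and 2 at 7 h. The dye effect of single features had standard deviations from 0.16 to 0.20, above that of the fold changes in each of the 6 pairs. Across features the 2 arrays of a pair correlated negatively, from -0.50 in the Wnt3A 4 h pair to -0.04 in the Wnt3A 9 h pair, so each value rests on averaging the dye swap.

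The first comparison asked which genes differ with Wnt3A, averaged over 4 h, 7 h and 9 h. ZCCHC12 had the largest mean value of the named genes, a log2 fold change of 0.94 ± 0.37 (SD, n = 3), with 0.55 at 4 h, 0.98 at 7 h and 1.29 at 9 h. WNT11, which encodes a Wnt ligand, was at 0.57 ± 0.18, and TNFRSF12A, a receptor of the TNF receptor family, was at 0.54 ± 0.11. INSIG1, a regulator of sterol synthesis, was at 0.49 ± 0.20, ID2, an inhibitor of basic helix-loop-helix transcription factors, at 0.44 ± 0.13, and INTS6L at 0.37 ± 0.12. On the other side stood GPCPD1, which encodes a glycerophosphocholine phosphodiesterase, at -0.57 ± 0.25, RWDD2B at -0.54 ± 0.30, FANCE, of the Fanconi anaemia core complex, at -0.48 ± 0.18, OARD1 at -0.37 ± 0.11, JMJD7 at -0.28 ± 0.10 and B3GALT4 at -0.26 ± 0.08. Each of these 12 genes had the same direction in 6 of 6 arrays, as the rule for named genes required.

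None of these genes passed the test over all features. limma called 0 of 28169 features, with the lowest adjusted p of 0.157 for TNFRSF12A, against 2609 at an unadjusted p under 0.05, where chance alone would give 1408. The other 11 named genes had limma adjusted p of 0.247. The count depended on how the spread was estimated: a fit with 1 coefficient per time point, whose spread comes from the 2 experiments at 7 h alone, called 364 features, and a fit to all 12 arrays with the pair as a block called 48.

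**Figure D1:**
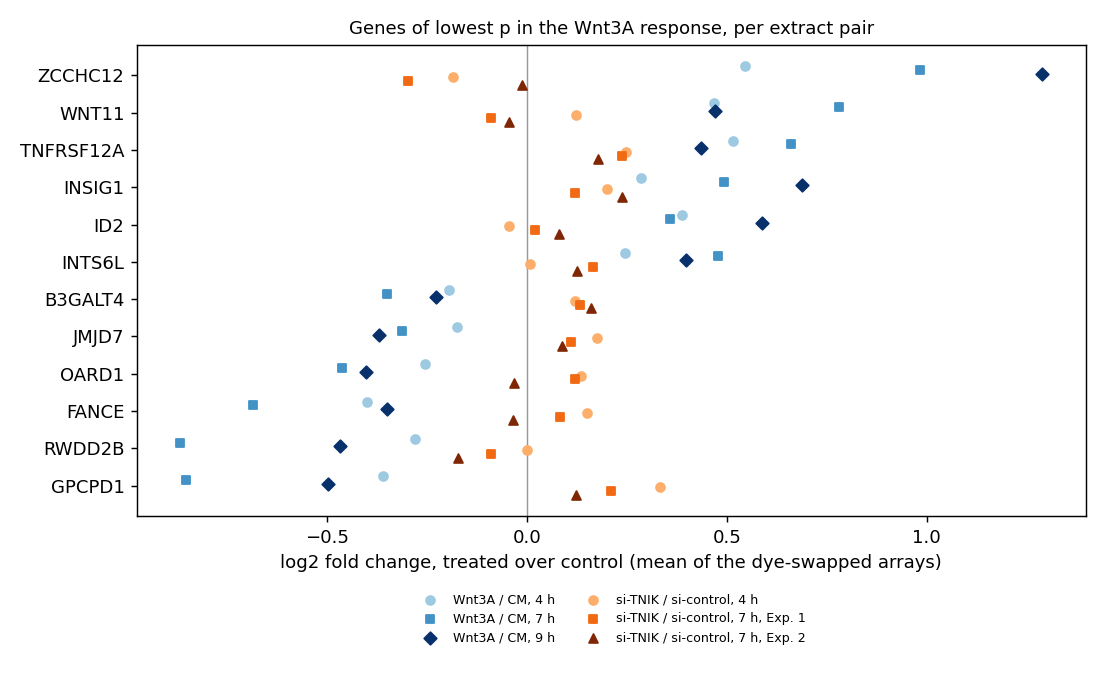
Log2 fold change (horizontal axis, treated over control) of the 12 genes of lowest p in the Wnt3A response, with 1 point per extract pair, blue for Wnt3A over CM and orange or brown for si-TNIK over si-control. By the rule that chose the genes, the 3 Wnt3A points of each lie on 1 side of 0, from 0.55 to 1.29 for ZCCHC12. None of the genes passed the limma test over all features.

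Wnt feedback and stem cell targets were higher with Wnt3A as a group. Of 16 measured Wnt feedback and stem cell targets, 12 had values above 0 and 3 rose when adjusted over the list alone, against 0 over all genes tested. These were AXIN2, a negative regulator of beta-catenin, at 0.34 ± 0.21, TCF7, a TCF transcription factor, at 0.33 ± 0.12, and NKD2, an antagonist of Dishevelled, at 0.31 ± 0.14. AXIN2 was named after its values were seen. The other probe of NKD2 was at 0.06. limma's camera called the list higher (adjusted p = 0.000356, or 0.187 with an estimated correlation), with medians of 0.05 at 4 h, 0.10 at 7 h and 0.23 at 9 h. The shift at 9 h stood on the swapped array, with a list median of 0.320 against 0.006 on the standard array. On the standard and swapped arrays the medians were 0.037 and 0.035 at 4 h and -0.004 and 0.035 at 7 h. The call was lost without the 9 h pair, as given below. Of 37 other reported Wnt targets, 4 rose when adjusted over the list alone and 0 over all genes: CCND1, which encodes cyclin D1, at 0.56 ± 0.27, ID2 at 0.44 ± 0.13, and, named after their values were seen, MSX2 at 0.31 ± 0.13 and MYC at 0.22 ± 0.09. That list was not called by camera (adjusted p = 0.0514), although it was with no background correction, with the processed intensities and with the deposited log ratios. The other probes of CCND1 were at 0.15 and 0.31. The sign of MYC turned on the standard arrays alone, as given below, so its value rests on averaging the dye swap. Of 40 Wnt pathway components, 0 passed over the list alone in limma; BTRC was at 0.22 ± 0.18 and CREBBP at -0.14 ± 0.06, and the list was not called (camera adjusted p = 0.236).

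G2/M genes were higher and G1/S genes lower with Wnt3A, although the G1/S genes were higher under median centring. Of 24 measured G2/M genes, 21 were above 0 and 9 rose when adjusted over the list alone, among them TOP2A at 0.30 ± 0.14 and BUB1B, a spindle checkpoint kinase, at 0.29 ± 0.10; 0 passed over all genes. The list was called higher by camera (adjusted p = 6.95e-08, or 0.428 with an estimated correlation), with medians of 0.01 at 4 h, 0.09 at 7 h and 0.32 at 9 h. At 4 h the list median was -0.20 on the standard array and 0.24 on the swapped array. The sign of BUB1B turned on the standard arrays alone, as given below. Of 25 G1/S genes, 19 were below 0 and 0 passed over the list alone; UHRF1 was at -0.30 ± 0.07 and CDT1, a replication licensing factor, at -0.30 ± 0.26. The list was called lower (camera adjusted p = 0.00206; adjusted p = 0.342 with an estimated correlation), but it was called higher with median centring (adjusted p = 0.0228) and was not called with the deposited log ratios (adjusted p = 0.0806).

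Genes of the unfolded protein and amino acid response were lower with Wnt3A, almost wholly in 1 pair. Of 24 measured members, 22 were below 0 and 1 fell when adjusted over the list alone, SDF2L1, an endoplasmic reticulum protein, at -0.77 ± 0.50; 0 passed over all genes. HSPA5, the main chaperone of the endoplasmic reticulum, was at -0.18 at 4 h, -0.30 at 7 h and -1.68 at 9 h. The list median was -0.02 at 4 h, -0.04 at 7 h and -0.97 at 9 h, and camera called the list lower (adjusted p = 1.02e-07; adjusted p = 0.522 with an estimated correlation). With median centring it was not called (adjusted p = 0.0571). The p53 targets were called lower (camera adjusted p = 0.000856; adjusted p = 0.342 with an estimated correlation) with 16 of 21 below 0 and 0 passing over the list alone, and DDB2 was at -0.27 ± 0.24 and TP53I3 at -0.18 ± 0.08. Median centring ended this call (adjusted p = 0.463).

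TGF-beta and BMP targets were called higher (camera adjusted p = 0.00206, or 0.187 with an estimated correlation). This was the only list also called by fry's directional test (adjusted p = 0.0426). Fry's test of changes in either direction called this list (adjusted p = 0.00163) and other reported Wnt targets (adjusted p = 0.000628). Of 20 measured members, 14 were above 0 and 2 rose when adjusted over the list alone, ID2 at 0.44 ± 0.13 and ID1 at 0.43 ± 0.19, both inhibitors of basic helix-loop-helix factors; 0 passed over all genes. The list was not called with median centring (adjusted p = 0.0571), where its median was 0.10 against 0.08 with loess. Ribosomal protein genes, taken as a sign of RNA quality, were called lower with loess but higher under median centring (camera adjusted p = 0.038; adjusted p = 0.522 with an estimated correlation), with 24 of 35 below 0 and 0 passing over the list alone. RPS15 was at -0.12 ± 0.04 and RPL4 at -0.12 ± 0.08, both above 0 with median centring. The direction of this list turned with no background correction, with the processed intensities and with the deposited log ratios, where it was not called, and with median centring, where it was called higher (adjusted p = 0.000166).

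The remaining 9 tested lists were not called by camera in the Wnt3A response with loess. Under median centring the calls became 6 higher and 0 lower, with cholesterol and fatty acid synthesis and the Wnt pathway components newly called higher. Of 26 AP-1 and immediate early genes, 2 rose when adjusted over the list alone, KLF10 at 0.50 ± 0.29 and IER3 at 0.30 ± 0.12 (list adjusted p = 0.981). Of 27 genes of cholesterol and fatty acid synthesis, 1 rose over the list alone, INSIG1 at 0.49 ± 0.20 (list adjusted p = 0.188). Of 27 actin and SRF or YAP targets, 1 rose over the list alone, VCL, which encodes vinculin, at 0.22 ± 0.14, and 2 fell, among them AMOTL2 at -0.28 ± 0.15 (list adjusted p = 0.981). Of 11 Notch targets, 1 rose, HES5 at 0.36 ± 0.30, and 1 fell, HEYL at -0.39 ± 0.30, over the list alone (list adjusted p = 0.620). In the interferon response (adjusted p = 0.825), hypoxia and glycolysis (0.620), histone genes (0.285), fibroblast markers (0.423) and neuronal markers (0.620), 0 genes passed limma over the list alone. RIGI was at -0.17 ± 0.14, SLC2A1, a glucose transporter, at -0.38 ± 0.23, LDHA at 0.19 ± 0.09, H2AX at -0.25 ± 0.24, S100A4 at -0.11 ± 0.09 and NEFM, a neurofilament, at 0.31 ± 0.13. H2AX was above 0 with median centring. With median centring the list median turned from -0.02 to 0.12 for histone genes, from 0.04 to -0.04 for Notch targets and from 0.01 to -0.02 for neuronal markers. The median of the actin and SRF or YAP targets, 0.0058, turned with no background correction, and it and that of the neuronal markers turned with the processed intensities and the deposited log ratios. The list of TNIK and related kinases had 2 measured members, too few to test, MAP4K4 at 0.15 ± 0.07 and MINK1 at 0.06 ± 0.02.

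All 7 list calls were lost without the 9 h pair. Camera then gave adjusted p of 0.106 for the Wnt feedback and stem cell targets, 0.354 for G2/M genes, 0.172 for G1/S genes, 0.106 for p53 targets, 0.981 for the unfolded protein and amino acid response, which turned to higher, 0.101 for TGF-beta and BMP targets and 0.172 for ribosomal proteins, while histone genes were called lower (adjusted p = 0.0071). The size of the shift was not largest at 9 h in each list: medians at 4 h, 7 h and 9 h were 0.04, 0.10 and 0.05 for TGF-beta and BMP targets, -0.0088, -0.10 and -0.10 for p53 targets and -0.08, 0.04 and -0.04 for ribosomal proteins. They were -0.06, -0.05 and -0.12 for G1/S genes. With the scan day as a block, added after seeing the data, the 7 calls stood and other reported Wnt targets were also called higher (camera adjusted p = 0.0372). By construction this block leaves each averaged fold change as it is and alters only the spread. It therefore cannot remove an effect of the day from the 9 h pair.

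**Figure D2:**
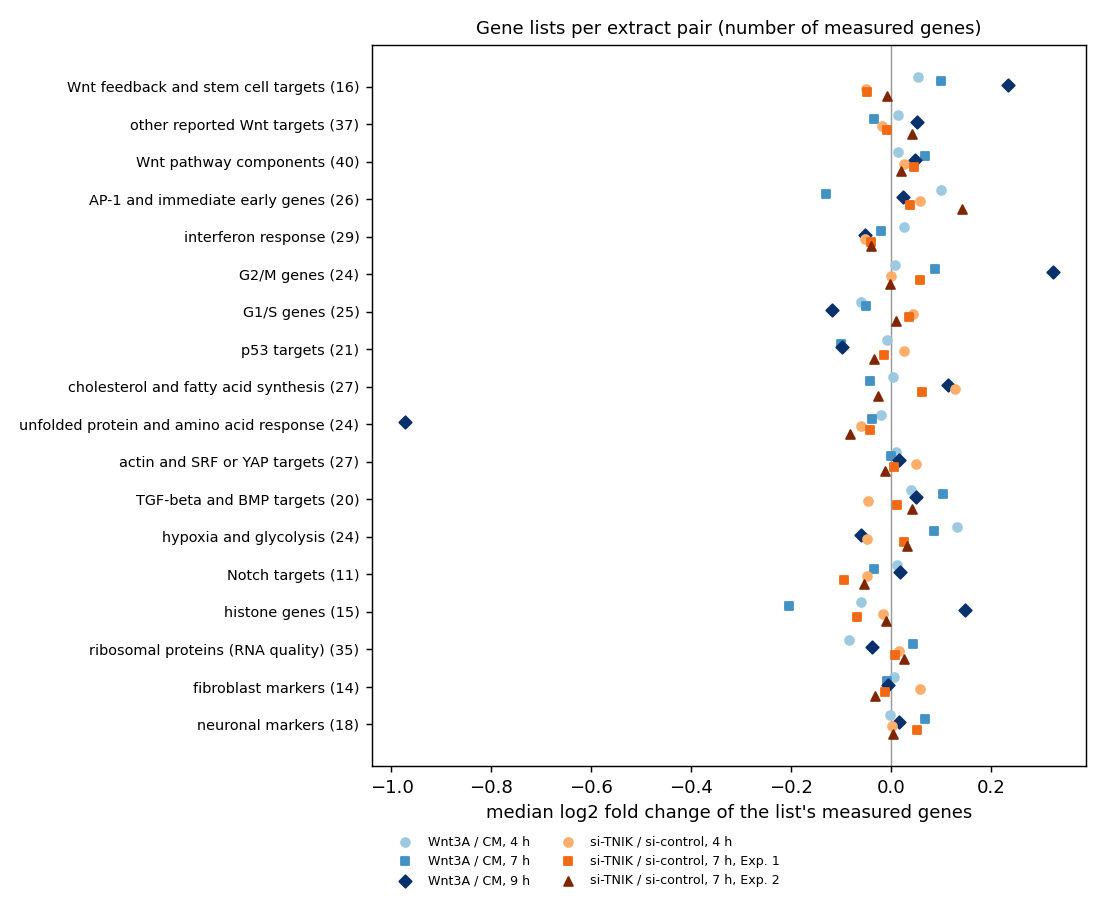
Median log2 fold change of the measured genes of each tested list (horizontal axis), 1 point per extract pair, with the number of measured genes in parentheses. The unfolded protein and amino acid response lies at -0.97 in the Wnt3A 9 h pair, and the other list medians lie between -0.20 and 0.32. With Wnt3A the median over all 3 pairs changes direction under median centring for G1/S genes, ribosomal proteins, histone genes, Notch targets and neuronal markers.

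The second comparison asked whether the Wnt3A response changes over time. limma called 0 of 28164 features for a change per hour, with the lowest adjusted p of 0.980, and 1254 had an unadjusted p under 0.05, fewer than the 1408 that chance alone would give. No gene was named from this test. Leaving out the 4 h pair gave 461 calls and leaving out the 7 h pair gave 89, in each case with a line through 2 points, and median centring gave 11481. Between pairs, fold changes across features correlated at 0.53 for 4 h and 7 h, but at -0.14 for 4 h and 9 h and -0.04 for 7 h and 9 h, and features are not independent replicates. The 4 h and 7 h pairs shared a slide and a scan day, and the 9 h pair was on another slide and day, so time and day cannot be told apart for it.

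The third comparison asked which genes differ when TNIK is lowered under Wnt3A, averaged over the 3 knockdown pairs. GLUL, glutamine synthetase, was at 0.32 ± 0.06 (SD, n = 3), SEC61A2, a subunit of a translocon of the endoplasmic reticulum, at 0.40 ± 0.25, KIF5C, a kinesin heavy chain, at 0.24 ± 0.08, PTPN18, a tyrosine phosphatase, at 0.24 ± 0.13, AGO4 at 0.21 ± 0.10 and C10orf88 at 0.17 ± 0.01. Lower values were those of FCGRT, the neonatal Fc receptor, at -0.56 ± 0.12, AP1S2, an adaptor complex subunit, at -0.39 ± 0.13, GPAT3 at -0.33 ± 0.04, CTSC, the protease cathepsin C, at -0.33 ± 0.07, ITM2C at -0.33 ± 0.08 and CYB561A3 at -0.32 ± 0.06. These 12 genes had the same direction in 6 of 6 arrays, as the rule for named genes required. None passed the test, with limma adjusted p of 0.292 for FCGRT and 0.541 for the other 11. The other probe of CTSC and of PTPN18 had the opposite sign.

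limma called 1 of 28169 features in the knockdown, against 2235 at an unadjusted p under 0.05, where chance alone would give 1408. It was the probe A_23_P135568, which fell by 1.92 on the log2 scale (± 0.30, limma adjusted p = 0.00109). The matching of accessions to the RefSeq gene table paired it with no symbol. Its values were -1.93 at 4 h and -2.21 and -1.61 in Experiments 1 and 2 at 7 h, and 0.07 ± 0.17 with Wnt3A in si-control cells. The probe A_24_P350576, also without a symbol, was at -1.30 ± 0.37 (limma adjusted p = 0.106). Which transcripts these probes read was not resolved by that matching and was not looked up otherwise. The call was lost with no background correction (adjusted p = 0.181) and with robust variance settings (adjusted p = 0.880), although A_23_P135568 was still at -1.78 and -1.92 in these. Without the Wnt3A 9 h pair, which lends its spread to the shared fit, 3 features were called. Without both pairs of scan day 2, an alternative added after seeing the data, 250 features were called, 48 higher and 202 lower. Each comparison then lay on 1 slide, so the spread was that within a slide. A slide effect cannot be told apart from the knockdown there. Among the called features were FCGRT at -0.62 and LRP6, a Wnt co-receptor, at -0.44. The other probe of LRP6 was at -0.02 at 4 h and 0.05 in Experiment 1, and the probe used was at -0.03 in Experiment 2.

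**Figure D3:**
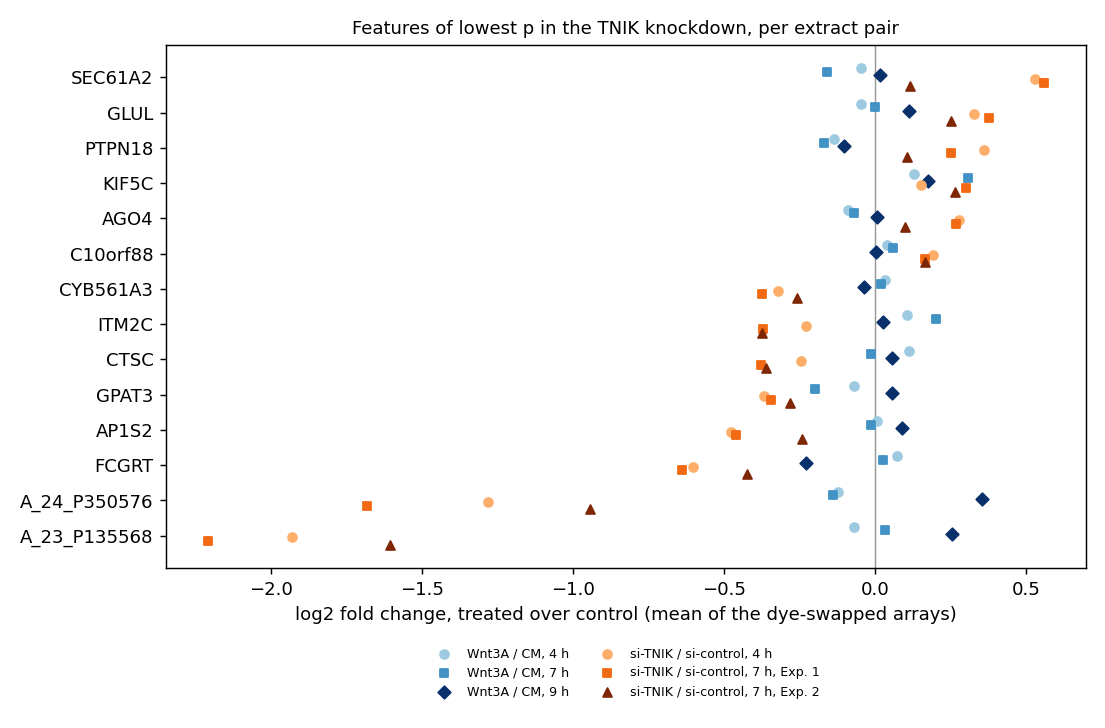
Log2 fold change (horizontal axis, treated over control) of the 12 genes of lowest p and of 2 probes without a symbol in the TNIK knockdown, 1 point per extract pair, orange or brown for si-TNIK over si-control and blue for Wnt3A over CM. The probe A_23_P135568, at -1.93, -2.21 and -1.61, is the only feature that passed the limma test, and it lies near 0 in the Wnt3A pairs at 4 h and 7 h.

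Wnt target lists were not called in the knockdown. Of 16 Wnt feedback and stem cell targets, 9 were below 0 and limma called 0 when adjusted over the list alone; NKD2 was at -0.19 ± 0.02 and SP5, a zinc finger factor, at -0.20 ± 0.17. The other probe of NKD2 was at -0.31, and the other probes of SP5 were at -0.02 and -0.05. The list medians were -0.05 at 4 h and -0.05 and -0.01 in Experiments 1 and 2 (camera adjusted p = 0.242). The median of the averaged fold changes was -0.04, against -0.08 with the deposited log ratios and with the processed intensities, -0.02 with no background correction and -0.01 with median centring. Of 37 other reported Wnt targets, 13 were below 0 and 0 passed over the list alone; PPARD was at -0.14 ± 0.06 and CCN4 at 0.12 ± 0.09 (camera adjusted p = 0.982). Of 40 Wnt pathway components, 0 passed over the list alone; LRP6 was at -0.30 ± 0.24 and BCL9, a beta-catenin cofactor, at -0.18 ± 0.04 (camera adjusted p = 0.922). The other probe of LRP6 was at -0.05. Of the kinases related to TNIK, MAP4K4 was at 0.10 ± 0.13 and MINK1 at 0.03 ± 0.04, and the probes of each differed in sign. MINK1 was below 0 with no background correction and with the deposited log ratios, and the median of both kinases was below 0 with the latter.

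AP-1 and immediate early genes were called higher in the knockdown (camera adjusted p = 0.0176; adjusted p = 0.901 with an estimated correlation), and interferon response genes lower (camera adjusted p = 0.0109; adjusted p = 0.901 with an estimated correlation). Of 26 AP-1 and immediate early genes, 24 were above 0 and 0 passed limma over the list alone. DUSP1, a phosphatase of MAP kinases, was at 0.29 ± 0.14 and IER5 at 0.15 ± 0.04, but the other probe of IER5 was at -0.46. Of 29 interferon response genes, 20 were below 0 and 0 passed over the list alone; IFI6 was at -0.24 ± 0.13 and IFIH1, a sensor of double-stranded RNA, at -0.14 ± 0.03. Both calls were lost without Experiment 2 (adjusted p = 0.472 for AP-1 and immediate early genes and 0.118 for the interferon response), where cholesterol and fatty acid synthesis was called higher (adjusted p = 0.042). The interferon list had like medians in the 3 pairs, -0.05 at 4 h and -0.04 and -0.04 in Experiments 1 and 2, while those of the AP-1 list were 0.06, 0.04 and 0.14. On the standard and swapped arrays the AP-1 list median was -0.02 and 0.13 at 4 h and -0.03 and 0.05 in Experiment 1. In Experiment 2 it was 0.16 and 0.14. The interferon list median was below 0 on each array. Both kept their direction and their call under each scaling run, median centring included. With the scan day as a block camera called both (adjusted p = 0.0082 each), but that block leaves the averaged fold changes as they are. It cannot remove an effect of the day from Experiment 2.

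The remaining 13 tested lists were not called in the knockdown with loess, and 4 of them were called higher under median centring (G2/M genes, G1/S genes, cholesterol and fatty acid synthesis and ribosomal proteins). Ribosomal proteins had 2 members that fell when adjusted over the list alone, RPS3 at -0.31 ± 0.19 and RPS15 at -0.22 ± 0.08, whose probes differed in sign; the list median was 0.01 while camera gave lower (adjusted p = 0.982). In the other 12 lists limma called 0 members over the list alone. Camera gave adjusted p of 0.982 for G2/M genes (CDK1 at -0.17 ± 0.03), 0.254 for G1/S genes (RRM2 at 0.16 ± 0.11) and 0.889 for p53 targets (BBC3 at -0.58 ± 0.37, with probes that differed in sign). It gave 0.289 for cholesterol and fatty acid synthesis (CYP51A1 at 0.23 ± 0.19), 0.242 for the unfolded protein and amino acid response (PHGDH at -0.24 ± 0.06), 0.982 for actin and SRF or YAP targets (FLNA at -0.33 ± 0.16 and CCN1 at -0.33 ± 0.16) and 0.934 for TGF-beta and BMP targets (TGIF1 at 0.17 ± 0.11). It gave 0.982 for hypoxia and glycolysis (ALDOA at -0.44 ± 0.31), 0.289 for Notch targets (HES5 at -0.24 ± 0.14), 0.242 for histone genes (H2BC4 at -0.10 ± 0.04), 0.922 for fibroblast markers (COL6A1 at -0.08 ± 0.03) and 0.922 for neuronal markers (TUBB3 at -0.24 ± 0.12, with probes that differed in sign). In the knockdown the list median was above 0 while camera gave lower for G2/M genes, p53 targets, actin and SRF or YAP targets, TGF-beta and BMP targets, ribosomal proteins and neuronal markers, and the mean was below 0 for p53 targets, actin and SRF or YAP targets and neuronal markers among these. With Wnt3A the AP-1 and immediate early genes had a median above 0 and a mean below 0. With median centring the knockdown median turned to above 0 for the unfolded protein and amino acid response, hypoxia and glycolysis, Notch targets and histone genes, and to below 0 for neuronal markers.

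At 7 h alone, with 2 experiments, limma called 0 of 28169 features for the knockdown, with the lowest adjusted p of 0.0608 and 1765 at an unadjusted p under 0.05, where chance alone would give 1408. For the difference between 7 h and 4 h it called 0 of 28158 features, with the lowest adjusted p of 0.0933 and 532 at an unadjusted p under 0.05, fewer than the 1408 that chance alone would give. Leaving out any 1 of the Wnt3A pairs gave 2 calls in each of these tests. Camera called AP-1 and immediate early genes higher at 7 h (adjusted p = 0.00757; adjusted p = 0.861 with an estimated correlation) and interferon response genes lower (adjusted p = 0.0225; adjusted p = 0.861 with an estimated correlation). It called 0 of 18 lists for the difference between 7 h and 4 h. The 2 experiments at 7 h correlated at 0.19 across features, while the 4 h pair and Experiment 1, which shared a slide, correlated at 0.45.

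The last comparison asked whether the knockdown acts on the genes that Wnt3A raises. Since limma called 0 genes higher with Wnt3A, the planned median over called genes had no value. In its place, as a choice made after seeing the data, the 100 named genes of lowest p among those higher with Wnt3A were read in the knockdown. Their median log2 fold change was -0.00448, with 51 of 100 below 0 and medians of -0.03 at 4 h, -0.01 in Experiment 1 and 0.02 in Experiment 2 at 7 h, so it did not exceed the spread between pairs (SD 0.03). The list was chosen on the same samples. With median centring the median was 0.10 and with the deposited log ratios -0.07. Leaving out 1 pair moved it from -0.05 without the Wnt3A 9 h pair to 0.04 without the 4 h knockdown pair.

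Across 28102 features, the mean fold changes of Wnt3A and of the knockdown correlated negatively, with Pearson r of -0.213 and a Spearman correlation of -0.198. Features are not independent replicates, so no p is given. The si-control Wnt3A extract is in the numerator of one comparison and the denominator of the other, and whether extracts were shared is not stated. In 20 simulated draws in which 2 extracts were shared, r was -0.335 with no common response, more negative than observed, while the covariance was -0.00153, less negative than the observed -0.00186. The draws put all of the fitted spread in the extracts and none in the arrays, so the shared part was at its largest. They therefore cannot tell whether extracts were shared. Within scan day 1 the 4 correlations between a Wnt3A and a knockdown pair were -0.36, -0.36, -0.47 and -0.26, and on scan day 2 the single correlation was 0.09. Of the 4, the 2 between pairs of different time points, which cannot share an extract, were -0.36 and -0.47. Over all pairs of different times, both scan days included, the covariance averaged -0.00109, against -0.00339 over pairs of the same time. Without the pairs of scan day 2, r between the means was -0.465, and with median centring over all pairs it was 0.342. Leaving out 1 pair gave -0.0654 without the Wnt3A 4 h pair, -0.0704 without 7 h, -0.385 without 9 h and -0.104 without the 4 h knockdown pair.

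**Figure D4:**
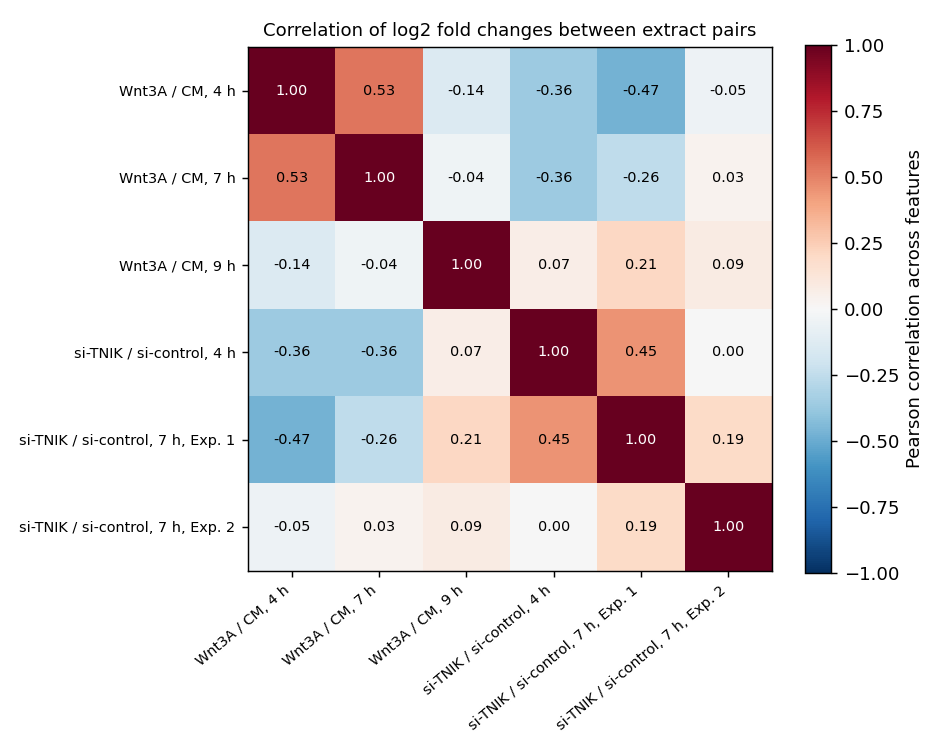
Pearson correlation across features of the log2 fold changes of each 2 extract pairs, from blue for negative to red for positive. The Wnt3A pairs at 4 h and 7 h correlate at 0.53 with each other and between -0.47 and -0.26 with the knockdown pairs of the same scan day, and the Wnt3A 9 h pair and knockdown Experiment 2, of the other day, correlate at 0.09.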

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

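The tests of the knockdown opposing the Wnt3A response across all genes and of the sign patterns of the Wnt3A pairs were chosen after the result was seen, and so was the comparison within scan days for the unfolded protein and amino acid response. Tests of a shared si-control extract and of a dye artefact at 9 h were also run, and both argued against the explanation, by correlations of -0.36 and -0.47 between day 1 pairs of different time points and by the same direction of the list on both arrays of the 9 h pair.

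The Wnt3A response of 8 gene lists differed between the time points by a test of the change per hour with limma's camera. Toward later times, lists were higher for G2/M genes (adjusted p = 8.31e-12; adjusted p = 0.461 with an estimated correlation), cholesterol and fatty acid synthesis (0.0177; adjusted p = 0.537 with an estimated correlation), histone genes (0.0177; adjusted p = 0.572 with an estimated correlation) and ribosomal proteins (0.048; adjusted p = 0.537 with an estimated correlation). They were lower for the unfolded protein and amino acid response (9.72e-21; adjusted p = 0.505 with an estimated correlation), p53 targets (0.0053; adjusted p = 0.461 with an estimated correlation), hypoxia and glycolysis (0.00984; adjusted p = 0.461 with an estimated correlation) and AP-1 and immediate early genes (0.0389; adjusted p = 0.537 with an estimated correlation). These changes per hour were tested with loess normalization alone. The list medians at 4 h, 7 h and 9 h did not change steadily in each list. They were 0.10, -0.13 and 0.02 for AP-1 and immediate early genes and -0.06, -0.20 and 0.15 for histone genes. For cholesterol and fatty acid synthesis they were 0.004, -0.04 and 0.11, and for ribosomal proteins -0.08, 0.04 and -0.04. Those of G2/M genes, the unfolded protein and amino acid response and hypoxia and glycolysis moved in 1 direction. Each time point is 1 pair and the 9 h pair was alone on its slide, so time cannot be told apart from slide and scan day for it.

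In the unfolded protein and amino acid response the 9 h pair stood apart, with list medians of -0.81 and -0.95 on its 2 arrays. Normalization is argued against, since the list median of the 9 h pair was -1.02 with the deposited log ratios and -1.03 with median centring. The single-colour level of the list was 1.00 above its mean over the 12 extracts in the 9 h CM extract and 0.11 above it in the 9 h Wnt3A extract, so high levels with CM or low levels with Wnt3A may account for the difference. The bound written before the test, the range of the 10 other extracts from -0.33 to 0.55, would have favoured high CM levels, but it was wrong because it mixed scan days: the 8 extracts of scan day 1 lay at or below -0.20, and the 2 other extracts of scan day 2 at 0.44 and 0.55, between the CM and the Wnt3A extract. Which extract departed cannot be told apart, and a Wnt3A effect at 9 h stays open, as untested.

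The 4 pairs of scan day 1 showed opposite fold changes for Wnt3A and the knockdown across features, which scan day 2 did not. Dye effects left after averaging are argued against, since the 4 correlations averaged -0.366 after the dye effects were regressed out. A knockdown that opposes the Wnt3A response across all genes stays open: the Wnt3A 4 h and 7 h pairs correlated at -0.00799 on average with knockdown Experiment 2, but the pattern was set to scan day 1 because of this pair, so the value decides nothing. A shared state of the si-control Wnt3A cultures stays open. Levels of the Wnt3A and si-control extracts correlated at 0.439 and 0.443, above the 0.2 it needs, but CM and si-TNIK extracts correlated more, at 0.669 and 0.496. The differences were -0.230 and -0.0535 (mean -0.142, SD 0.125) where it needs positive ones, so its prediction was not met. However, the levels were taken against each gene's mean over the extracts of both scan days. Extracts of scan day 1 therefore share the offset of their day, which can raise all these correlations, so the test cannot decide. An effect of the slide also stays open, because slide, scan day and extracts change together.

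For the number of genes called, the signs of the 3 pairs of a comparison can be turned in 4 ways, too few for a share under 0.05. The real signs of the Wnt3A pairs called 0 genes and the highest other pattern 0, so 4 of 4 patterns gave as many. In the knockdown the real signs called 1 feature and the highest other pattern 0, so 1 of 4 patterns gave as many.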

How the results depend on the processing

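Alternatives with the scan day, without scan day 2 or with dye regression, the gene lists under most scalings, and every value for the 100 genes were chosen after seeing the data. Over all alternatives the named genes gave 2614 values on the same side of 0 and of the test threshold as in the report, 89 that passed the test only in the alternative, 2 that lost it and 51 with the sign turned. Where no reason is stated, the cause was not tested. The share of spots with red signal well above background ran from 66.2% to 85.8% on scan day 2 and from 74.7% to 85.0% on scan day 1, and what this limits was not tested.

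With 1 dye orientation the dye effect is not cancelled by construction. Standard arrays alone called 400 features for Wnt3A, 17 for the knockdown and 1 at 7 h. In these, Wnt3A values turned for MAP4K4 (-0.068), BUB1B (-0.016), RPS15 (0.17), NEFM (-0.30) and MYC (-0.46). Knockdown values turned for SP5 (0.010), PPARD (0.015), MAP4K4 (-0.10), IFI6 (0.0036), NUSAP1 (-0.20), INSIG1 (-0.080), P4HA1 (-0.20), H2BC4 (0.030), RPS3 (0.0024), AXIN2 (-0.028), MYC (-0.68), ID2 (-0.20) and MSX2 (0.032). Swapped arrays alone called 53 features for Wnt3A, 276 for the knockdown and 1 for 7 h minus 4 h. In these, Wnt3A values turned for CDT1 (0.13), VCL (-0.011) and H2AX (0.29). Knockdown values turned for MINK1 (-0.068), IFIH1 (0.0041), CDK1 (0.042), TYMS (-0.14), SLC7A11 (0.11), FLNA (0.047), HES5 (0.017), NOTCH3 (0.072), H1-10 (0.034), ELAVL3 (-0.042) and CCND1 (0.15).

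Median centring gave 11481 features for the Wnt3A change per hour, 6 lists in the knockdown (5 higher, 1 lower), 6 lists with Wnt3A (6 higher, 0 lower, against 3 and 4), a correlation of 0.342 between the comparisons and a median of 0.10 for the 100 genes. It turned H2AX (0.014), RPS15 (0.16) and RPL4 (0.16) with Wnt3A and COL6A1 (0.018) in the knockdown. With no background correction the knockdown called 0 features and MINK1 was at -0.012. The processed intensities, the deposited log ratios and the series table each called 2 in the knockdown. RPS15 with Wnt3A was at 0.019, 0.025 and 0.025 in these, and MINK1 in the knockdown at -0.046, -0.068 and -0.068. The deposited log ratios put the 100 genes at -0.067. The mean over the probes of a gene turned MINK1 (-0.012), IER5 (-0.15), MYC (-0.0016) and ID2 (-0.00042) in the knockdown.

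Robust variance settings called 0 features in the knockdown. All 12 arrays with the pair as a block called 48 for Wnt3A, 2 in the knockdown and 2 at 7 h; the estimated correlation of the arrays of a pair was -0.00177, so that fit treats them as nearly independent. One coefficient per time point called 364 for Wnt3A and 6 in the knockdown, the knockdown pairs alone 2, and equal weight per time point 3. At an adjusted p under 0.1, 1 feature was called at 7 h and 1 for 7 h minus 4 h. With an estimated correlation 0 lists were called in either comparison, against 2 and 0 at an unadjusted p under 0.05. Fry's directional test called 1 list with Wnt3A and 0 in the knockdown, where 1 had an unadjusted p under 0.05.

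Without scan day 2, where each comparison lay on 1 slide, 250 features were called in the knockdown, 1 list with Wnt3A and 1 in the knockdown. In that setting r was -0.465 and ID2 was at -0.013 in the knockdown. The scan day as a block called 2 features in the knockdown. Dye regression turned MYC (-0.073) and ID2 (-0.032) in the knockdown. The 100 genes chosen at 7 h and 9 h and read at 4 h were at -0.051, and those chosen at 4 h and 9 h and read at 7 h were at 0.0017.

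Leaving out each pair gave 0 to 0 features for Wnt3A, 1 to 3 for the knockdown, 0 to 461 for the change per hour, 0 to 2 at 7 h and 0 to 2 for 7 h minus 4 h. It gave 1 to 9 lists with Wnt3A, 1 to 3 in the knockdown, r from -0.385 to -0.0654 and a median of the 100 genes from -0.052 to 0.039. ID2 in the knockdown ran from -0.013 without Experiment 2 to 0.050 without the 4 h pair. A lone pair is assumed to vary like the others. The planned median over genes called higher with Wnt3A had no value in the report; alternatives that called such genes gave 0.22 with standard and 0.33 with swapped arrays alone, -0.018 with 12 arrays and 0.019 with 1 coefficient per time point. No value for TNIK could be given, nor for 7 h minus 4 h without the 4 h knockdown pair.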

Other observations

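The matched draws below were planned before their result was seen, and the genes of the largest values in single pairs were chosen after the values were seen.

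In the single pairs, at least 1.5-fold higher values were seen for 7 features at 4 h, 40 at 7 h and 134 at 9 h with Wnt3A, and at least 1.5-fold lower values for 2, 191 and 147. In the knockdown, 6 features were higher and 23 lower at 4 h, 8 higher and 199 lower in Experiment 1, and 15 higher and 25 lower in Experiment 2. EGR1, an immediate early transcription factor, was at 0.86 in the Wnt3A pair at 4 h, -0.56 at 7 h and 0.91 at 9 h. DDIT4, an inhibitor of mTOR signalling, was at 0.52 at 4 h, 0.98 at 7 h and -0.16 at 9 h. HSPA1A, a heat shock chaperone, was at 0.60 at 4 h, 0.89 at 7 h and -1.85 at 9 h, so each of these 3 genes differed in sign between pairs. These are values of 1 pair each and were not tested one by one.

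A hypothesis was that the knockdown lowers the Wnt list genes that Wnt3A raises more than it lowers other genes of like Wnt3A fold change. The 7 genes that passed over their list with Wnt3A (AXIN2, CCND1, ID2, MSX2, MYC, NKD2 and TCF7) had a median knockdown log2 fold change of -0.07, with 4 of 7 below 0. Among 10000 draws of 7 genes matched on the Wnt3A fold change this median lay at the 8.48th percentile, above the bound of 2.5 set before the test. The median of the draws was 0.0039. The 7 genes had medians of -0.12 at 4 h and of -0.03 and -0.03 in Experiments 1 and 2, each below 0, but by the bound set before the test the prediction of the hypothesis was not met. Single values ran from -0.19 ± 0.02 for NKD2 to 0.07 ± 0.10 for AXIN2 (SD, n = 3).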
